A study of Bos taurus with 47 samples.

How the data were processed

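Muscle RNA of 47 bovine samples was prepared as non-directional, polyA-selected libraries and sequenced as 150 bp read pairs, per the labels' protocols. The authors deposited whole-number counts of reads per gene in 3 tables, 1 per stage, with 27607 identifiers each. Per the submitters' processing notes, FastQC 0.11.8, MultiQC 1.9, STAR 2.7.3a and edgeR 3.24.3 were used. The genome build, annotation and counting program are not given in the sources used here. As the library kit does not mark strand, reads of overlapping genes on opposite strands cannot be told apart. In the slaughter table the header lacks a cell for the identifiers, and the first name was taken to head the first column of values. Sample groups came from the treatment and timepoint labels. No per-sample column was left unused.

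The counts were analysed in R 4.3.3. Genes passing filterByExpr of edgeR 4.0.16 were scaled by TMM and tested with edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. LG was compared with MG within each stage, stages were compared through the mean of their LG and MG groups, and the interaction was tested in 1 model over 47 libraries. Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with sample weights and, added after seeing the data, without them, 1 surrogate variable from sva 3.50.0, DESeq2 size factors, no filter, a stricter filter of 1 CPM in every library of a group, adjusted p under 0.10, unadjusted p under 0.01 with an absolute log2 fold change over 0.5, and leaving out each library in turn. CPM values for display use TMM-scaled library sizes. The SD is between libraries. Separate animals are not stated for each number, so p-values measure the spread between these libraries. As a check for a library deposited again under another name, pairs of libraries of 1 group were compared by chi-square, which was 25.2 or more per degree of freedom over 161 pairs, so none was merged. Whether libraries share an animal is not tested by this.

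The rule for naming genes, fixed before the data were examined along with the designs and alternatives, needed gene symbols. A symbol could be assigned to 0 identifiers, since the reference gene table used here carries no matching identifier. The rule was therefore replaced by 2 identifiers per direction, those with the smallest p for LG against MG and those with the largest change among stage calls with a mean log2 CPM of at least 3. The gene lists, cell type markers and fetal sex covariate fixed beforehand were not run for the same reason. Floors use 3 counts and intervals are 95%. Permutation tests drew 100 permutations for effect correlations and 10000 for number matching, where every arrangement was listed instead for birth with slaughter and birth with fetus. Other splits of the libraries numbered 100 per LG and MG comparison and 40 for the other models, the real split included, and limma voom with sample weights was run over the LG, MG and interaction splits too. For the interaction, the library number was also entered as a random block through limma's duplicateCorrelation.

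The edgeR steps were tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold, and on the real libraries with genes thinned by the same folds. In the simulation for slaughter against birth, 82.1% of the 67 genes set to 2-fold were recovered, among 13218 genes tested. For birth against fetus it was 71.6% of 67, among 14482. As only 200 genes were changed, the scaling was not tested with most genes changed, as in the real stage comparisons. In the simulated interaction of birth and slaughter, 20.9% of 67 genes set to 2-fold and 72.7% of 66 set to 4-fold were recovered, among 14509 tested. The genes with a wide gap between libraries were chosen after seeing the data, and gaps of 2-fold, 2.3-fold, 2.8-fold and 4-fold were all tried.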

Results

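Messenger RNA was measured in the Longissimus muscle of cattle whose dams or granddams, crossbred Angus heifers of the F0 generation, gained weight slowly (LG, 0.28 kg per day) or moderately (MG, 0.79 kg per day) over the first 84 days of gestation. Both sets of F0 heifers were kept together afterwards. The series held 47 libraries. At birth, F1 heifer calves gave 8 LG and 8 MG libraries. At slaughter, F1 heifers gave 8 LG and 7 MG libraries by the sample labels, while the protocol text states 7 LG and 8 MG, and the labels were followed. F2 fetuses of day 84 gave 8 LG and 8 MG libraries. Total counts ran from 13308433 to 32547565 per library. A count of 3 in the deepest library corresponded to 0.0922 CPM, the count scaled to library size. Every table listed the same 27607 gene identifiers, of which 23108 had a count in at least 1 library. The tables carried no gene symbols and the files do not pair the identifiers with names, so genes are given by identifier and no gene group is described.

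Stage separated the libraries far more than maternal gain did. The first principal component of log2 CPM held 67.8% of the variance over 47 libraries, and the second held 10.3%. Fetal muscle spread its counts over many genes. In fetuses, 447 ± 59.8 genes (SD, n = 16) held 50% of a library's counts, against 83.4 ± 26.2 at birth (n = 16) and 57.5 ± 6.41 at slaughter (n = 15). The 10 most abundant genes took 11.5% ± 1.44 of counts in fetuses, 23.7% ± 2.28 at birth and 23.8% ± 1.16 at slaughter. A level of at least 1 CPM in every library of a stage was reached by 10204 genes in fetuses, 10424 at birth and 10552 at slaughter. Of these, 8710 reached it at all 3 stages, 960 in fetuses alone and 1240 at both F1 stages but not in fetuses.

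**Figure D1:**
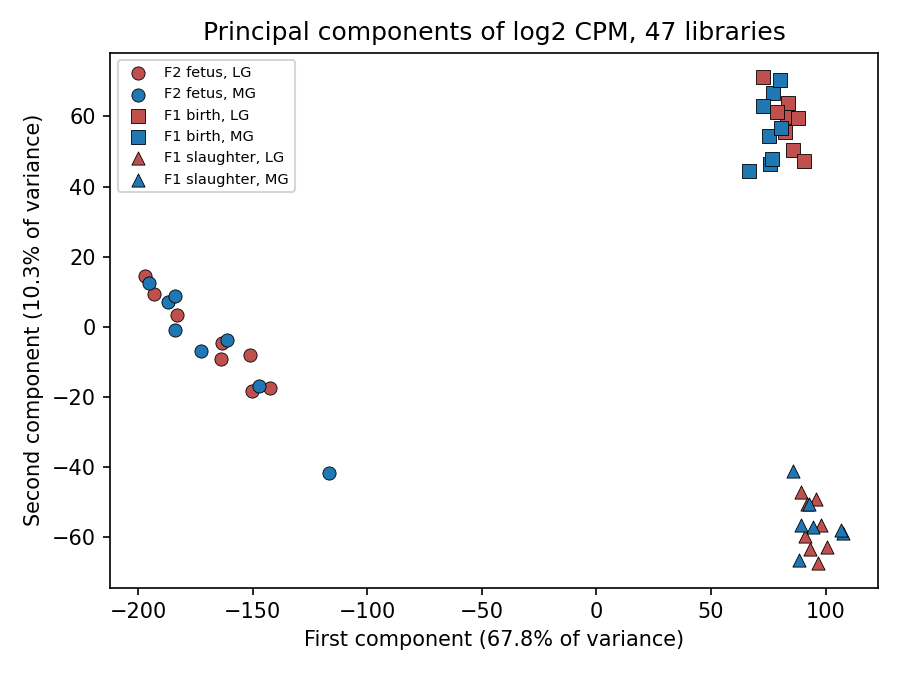
First and second principal components of log2 CPM for the 47 libraries, with the share of variance on each axis. Symbols mark the stage and colours mark LG or MG. The first component holds 67.8% of the variance.

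**Figure D2:**
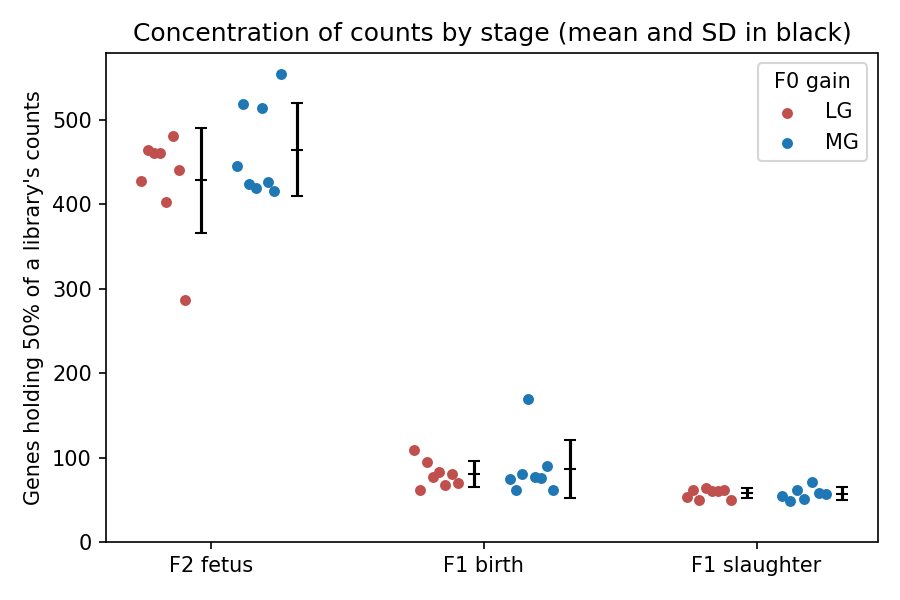
Number of genes that together hold 50% of a library's counts (vertical axis, from 0), 1 point per library, by stage and F0 gain, with mean and SD in black. Fetal libraries average 447 genes, birth libraries 83.4 and slaughter libraries 57.5.

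The comparison of LG with MG at birth asked whether slow gain of the dam in early gestation left a difference in the muscle of newborn F1 heifers. No gene passed the threshold out of 12485 tested with edgeR's quasi-likelihood test (0 at adjusted p under 0.05). An unadjusted p under 0.05 was reached by 515 genes, where a rate of 0.05 gives 624 and other splits of these libraries had a median of 554. Of these 515, 158 were higher and 357 lower in LG, and without LG library 05 the 515 became 1023, still with 0 past the threshold. DESeq2 and limma voom with sample weights also called 0 genes, with 547 and 659 at an unadjusted p under 0.05, and the count was 1299 of 21145 genes with edgeR and no filter on low counts. The identifiers with the smallest p in each direction did not pass. ENSBTAG00000006572 averaged 0.502 ± 0.168 CPM in LG and 1.17 ± 0.449 in MG (SD, n = 8 each), a log2 fold change of -1.23 (SE 0.28, edgeR adjusted p = 0.985), and ENSBTAG00000023472 averaged 9.33 ± 1.28 and 13.2 ± 2.48 CPM, a log2 fold change of -0.50 (SE 0.13, edgeR adjusted p = 0.985). ENSBTAG00000047600 had a log2 fold change of 2.54 (SE 0.67) and ENSBTAG00000000522 of 2.39 (SE 0.66), both with an edgeR adjusted p of 0.985. For these, LG library 25 stood far above the others, and without it the values were 1.54 and 1.19. With limma voom and sample weights they had 1.96 and 1.33, and with 1 surrogate variable in edgeR 1.71 and 1.54. The interval of the LG to MG ratio lay within 2-fold for 91.9% of genes and within 1.5-fold for 68.2% (95% limma voom intervals). In simulated data of the same size, 44.8% of genes set to a 1.5-fold change and 74.6% of those set to 2-fold were recovered, and 58.2% and 70.1% when genes of the real libraries were thinned by these folds. Here and below, 200 genes were changed at once. The adjustment is stricter when fewer genes change, so isolated changes would be recovered less often.

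At slaughter, the same question was asked of F1 heifers after growth under common management. Of 12577 genes tested with edgeR, 0 passed, and 230 had an unadjusted p under 0.05. A rate of 0.05 gives 629, and other splits of these libraries had a median of 480. Of the 230, 142 were higher and 88 lower in LG, and without LG library 07 the 230 became 377, with 0 past the threshold. DESeq2 and limma voom with sample weights called 0 genes as well, with 253 and 365 at an unadjusted p under 0.05, and the count was 768 of 20796 genes with edgeR and no filter. ENSBTAG00000017524 averaged 7.95 ± 2.52 CPM in 8 LG libraries and 3.78 ± 1.80 in 7 MG libraries, a log2 fold change of 1.07 (SE 0.27, edgeR adjusted p = 1.00). ENSBTAG00000007666 had 0.99 (SE 0.25), ENSBTAG00000004769 had -1.26 (SE 0.30) and ENSBTAG00000001112 had -0.68 (SE 0.18) on the log2 scale, none of which passed. The interval of the ratio lay within 2-fold for 91.5% of genes and within 1.5-fold for 67.3%. In simulated data of the same size, 40.3% of genes set to a 1.5-fold change and 76.1% of those set to 2-fold were recovered, and 32.8% and 64.2% in the thinned real libraries.

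In fetuses of the F2 generation, the comparison asked whether a difference reaches a further generation. Of 14200 genes tested with edgeR, 0 passed and 102 had an unadjusted p under 0.05, with 55 higher and 47 lower in LG. A rate of 0.05 gives 710, and other splits of these libraries had a median of 374. Fetal MG library 20 lay farthest out on the first component of the fetal libraries. Without it the 102 became 380, without MG 45 they became 209 and without LG 29 they became 195, each with 0 past the threshold. DESeq2 called 0 genes and had 215 at an unadjusted p under 0.05. Limma voom with sample weights called 0 and had 2794, against 118 without the weights, which ran from 0.181 for MG 20 to 3.55 for LG 14. A single edgeR model over all 47 libraries called 2, both higher in LG, with 398 at an unadjusted p under 0.05. ENSBTAG00000043567 averaged 437 ± 305 CPM in LG and 176 ± 48.1 in MG (SD, n = 8 each; log2 fold change 1.31, SE 0.39, edgeR adjusted p = 1.00). ENSBTAG00000017681 had a log2 fold change of 1.49 (SE 0.46), ENSBTAG00000019794 of -0.35 (SE 0.12) and ENSBTAG00000040518 of -1.83 (SE 0.65), none of which passed. With limma voom and sample weights, ENSBTAG00000017681 had 0.59 and ENSBTAG00000040518 had -1.13. The interval, from limma voom with sample weights, lay within 2-fold for 68.5% of genes and within 1.5-fold for 40.2%, fewer than in the F1 stages. With these weights, other splits of the fetal libraries had a median of 1884 genes at an unadjusted p under 0.05. The fetal intervals may therefore be too narrow. Of genes set to a 1.5-fold change in simulated data of the same size, 2.99% were recovered, against 37.3% of those set to 2-fold and 75.8% of those set to 4-fold. In the thinned real libraries these were 1.49%, 34.3% and 78.8%, so 1.5-fold effects were rarely detected in the fetuses at this number of libraries.

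**Figure D3:**
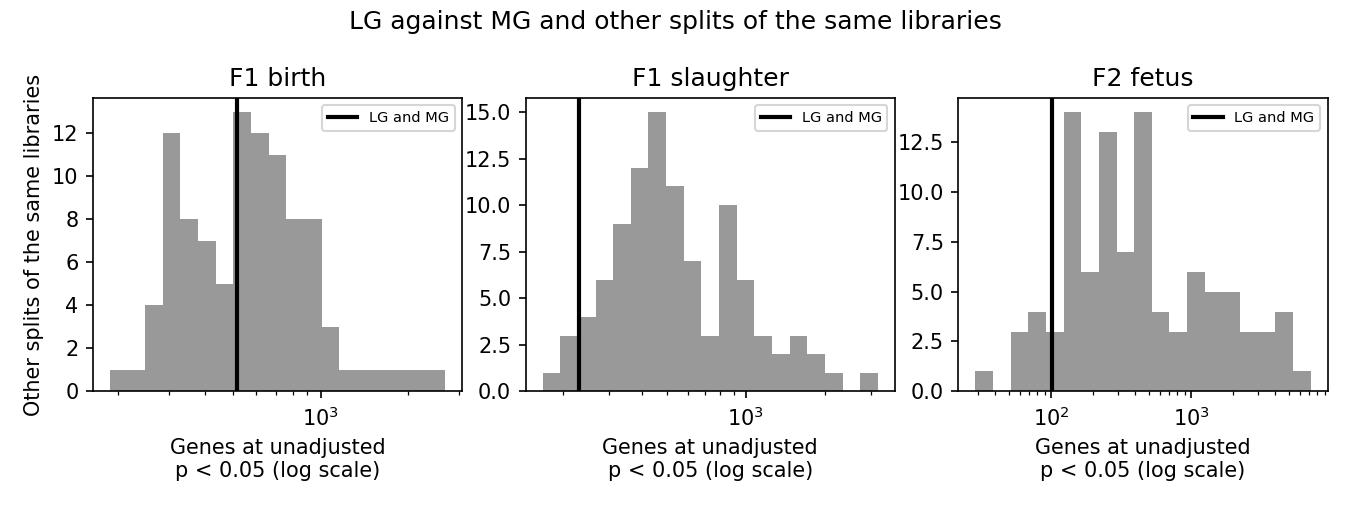
Genes with an unadjusted p under 0.05 (horizontal axis, log scale) for the other splits of the same libraries among 100 drawn at each stage (grey bars) and for LG against MG (black line). The LG and MG counts are 515 at birth, 230 at slaughter and 102 in fetuses.

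Whether maternal gain acted differently between stages was tested over 15264 genes in a single edgeR model. It shared 1 spread per gene over all stages, while the median SD within groups was 0.51 log2 CPM in fetuses, 0.31 at birth and 0.30 at slaughter. Contrasts with fetuses may therefore be too lenient, and that of birth with slaughter too strict. For the latter, 20.9% of genes set to 2-fold were recovered in simulated data. Recovery was not simulated for contrasts with fetuses. The difference of LG-minus-MG effects passed for 0 genes between birth and slaughter, 0 between slaughter and fetus and 0 between birth and fetus. An unadjusted p under 0.05 was reached by 468, 341 and 449 genes. A rate of 0.05 gives 763, and other splits of the libraries had medians of 490, 822 and 880. Limma voom with sample weights called 0 in each, with 514, 2168 and 2112 genes at an unadjusted p under 0.05, and without weights 0 in each, with 164, 206 and 325. The LG-minus-MG effects did not correlate across genes between stages beyond permuted labels. Spearman's rho was 0.0527 between birth and slaughter (11986 genes), 0.0568 between slaughter and fetus (12067 genes) and 0.0712 between birth and fetus (12031 genes), with permutation p of 0.693, 0.743 and 0.683 from 100 two-sided permutations each and 0.743 for all 3 after Benjamini-Hochberg adjustment. Genes are not independent replicates.

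Muscle at slaughter differed from muscle at birth in most genes. With edgeR, 9390 of 13369 tested genes changed (70.2%), 4944 rising and 4446 falling towards slaughter. The majority turned to falls in MG libraries alone (3452 rising, 3815 falling) and over the libraries of the 6 numbers that occur at both stages, with the number as a block (3371 and 3775) and without it (3453 and 3679 over the same genes, 3213 and 3510 with their own filter), so neither direction prevailed throughout. Changes beyond 2-fold were fitted for 1810 rises and 1329 falls, and beyond 8-fold for 153 and 104. ENSBTAG00000009489 rose by 7.79 on the log2 scale (SE 0.27, edgeR adjusted p = 6.12e-21), from 0.134 ± 0.177 CPM at birth (SD, n = 16) to 26.1 ± 6.79 at slaughter (n = 15). ENSBTAG00000010981 rose by 6.72 (SE 0.30). ENSBTAG00000008026 fell from 135 ± 83.2 CPM to 6 counts in 5 of 15 libraries, and ENSBTAG00000051102 fell by 5.98 on the log2 scale (SE 0.27), from 47.4 ± 20.9 to 0.742 ± 0.465 CPM. When a change of more than 2-fold was itself tested, 1839 genes passed. The counts of each stage were deposited apart, so stage cannot be told apart from collection or library batch here.

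The step from fetus to birth was wider still. With edgeR, 12141 of 14820 tested genes changed (81.9%), 5619 rising and 6522 falling towards birth, and 737 rises and 1706 falls exceeded 8-fold. The median log2 fold change of all genes was -0.12 with TMM scaling and -0.16 with DESeq2 size factors, and the changes given here are relative to the TMM scaling. ENSBTAG00000020080 rose by 11.99 on the log2 scale (SE 0.23, edgeR adjusted p = 1.71e-29), from 1.53 ± 0.574 CPM in fetuses to 6265 ± 1271 at birth (SD, n = 16 each). ENSBTAG00000019554 rose by 12.49 (SE 0.32). ENSBTAG00000002066 averaged 479 ± 183 CPM in fetuses and had 0 counts in the 16 birth libraries, which makes it at least 34350-fold lower at birth against a floor of 3 counts over the group. ENSBTAG00000000177 averaged 51.1 ± 24.9 CPM in fetuses and had 1 count at birth, a ratio of 10860 with a counting interval of 1949 to 428900 (95% exact Poisson, counting error only). When a change of more than 2-fold was itself tested, 7079 genes passed. Between fetus and birth, stage goes together with generation, with the muscle region sampled and with any difference in collection or library batch. These cannot be separated in the comparison.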

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

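The tests of fetal spread by thinning depth, by leaving out MG 20 and LG 41, by the variance between LG and MG means and by the component's weights, those of the shifted names, of chance matching and of the best match, and the counts of splits with edgeR were written down after their results had been seen; those of the most abundant genes, of carried-over reads, of the splits along the first component and of the splits with limma voom were written before. Of 58 groups of values examined for a single library far from the rest, 12 held one, where chance gives about 1 in 20. Birth MG library 17 detected 17680 genes, needed 169 genes for 50% of its counts and gave 17.3% of them to its 10 most abundant genes. Slaughter MG library 47 had 32.5 M counts, and fetal LG library 41 needed only 287 genes for 50% of its counts. A run of 37 adjacent rows of the fetal table, singled out for its high counts, took 7.29% of counts in slaughter LG library 14, 5.19% in fetal LG library 22 and 5.54% in fetal MG library 20. Among the named identifiers, birth LG library 25 had 16.3 CPM of ENSBTAG00000047600 and 90.8 CPM of ENSBTAG00000000522, slaughter LG library 02 had 13.5 CPM of ENSBTAG00000017524 and slaughter LG library 29 had 1.09 CPM of ENSBTAG00000004769.

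Fetal libraries varied more than F1 libraries, with a median SD within groups of 0.51 log2 CPM against 0.31 at birth and 0.30 at slaughter over 11691 genes, and a first component holding 49.9% of their variance. Thinning to the smallest total left 50.04% on that component, leaving out the 100 genes with the most counts left 49.7% and leaving out MG 20 and LG 41 left 45.7%. These values argue against depth, a few dominant genes or those 2 libraries as the whole cause of the component's share. A share can hold while the spread shrinks, and the SD was not computed again. For the wider spread itself, thinning or leaving out therefore decides nothing. Total counts averaged 18.1 ± 2.07 M in fetuses (SD), 18.5 ± 2.54 M at birth and 19.5 ± 4.22 M at slaughter. The 10 most abundant genes took 11.5% of counts in fetuses, against 23.7% at birth and 23.8% at slaughter. Fetal depth was thus close to F1 depth and no more variable. These values argue against depth or a few dominant genes as the cause of the wider spread. MG 20 and LG 41 as its cause stay undecided. LG and MG means held 3.49% of the variance between fetal libraries, where labels at random give 6.67% on average. This argues against maternal gain, as a difference of group means, as the cause of the component's share. It tests nothing about the SD within groups, which leaves out such a difference by construction. Weights of the component followed the birth-minus-fetus change across genes with a rho of 0.328, so differences in developmental progress or in the tissue dissected may contribute, and these cannot be told apart since no label gives either per fetus.

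A count of 0 genes is reached by every split, so the 100 of 100 splits that gave as many at birth (highest other 215), slaughter (3) and in fetuses (3406) decide nothing, nor do the 40 of 40 for the interactions of birth with slaughter (28), slaughter with fetus (3880) and birth with fetus (5011). At an unadjusted p under 0.05, chance cannot be excluded for LG against MG: with edgeR 58, 96 and 91 of 100 splits gave as many genes as the 515, 230 and 102 at birth, at slaughter and in fetuses (highest other 2440, 2908 and 6508), and with limma voom and sample weights 50, 91 and 39 gave as many as the 659, 365 and 2794 (highest other 2398, 2939 and 8034). Nor can it be for the interactions of birth with slaughter, slaughter with fetus and birth with fetus, where 25, 40 and 37 of 40 splits gave as many with edgeR (468, 341 and 449; highest other 1177, 6280 and 6797) and 38, 20 and 20 with limma voom (514, 2168 and 2112; highest other 2391, 6796 and 7179). For the stages, only the real split, 1 of 40, reached 9390 genes (highest other 3960) and 12141 genes (highest other 6297), which argues against chance. A difference in collection or library batch that goes with stage would give the same, so these splits do not single out stage.

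Splits of the fetal libraries with so many calls point to a structure among them. Over the 100 fetal splits, edgeR's genes at an unadjusted p under 0.05 rose with the difference in mean score on the first component (rho = 0.70). That follows from the component's share of the variance and tests no cause, so the source of the structure stays open. No difference between LG and MG was detected on it (exact permutation p = 0.996, two-sided).

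Over 11 genes whose levels split the libraries of both stages by a gap of over 4-fold, birth and slaughter libraries sharing 1 of 6 numbers had a mean r of 0.808, against -0.130 for other pairs (exact permutation p = 0.0208, one-sided, the smallest that 48 arrangements can give). Shifting the slaughter names gave a mean r with birth of at most 0.304, which argues against shifted names in the slaughter table. Numbers matched by chance reached the slaughter and fetus value over genes with a 4-fold gap with a permutation p of 0.0005, one-sided. Over all 12067 genes this permutation p was 0.2998, and with a 2-fold gap 0.0868. Gaps of 2.3-fold and 2.8-fold gave 0.0002 and 0.0004. Chance is therefore argued against only for genes with a gap of 2.3-fold or more, chosen after seeing the data. Shifted fetal names reached at most 0.171 with slaughter, below the 0.487 of the deposited names over 15 numbers, but 0.315 with birth, above the 0.257 of the deposited names over 7 numbers, so these rows differ on a shift in the fetal table. Over the 5 genes for slaughter and fetus, the highest level of the lower stage was a median of 26.2% of the other's, from 4.36% to 92.3%. A gap of over 4-fold at both stages favours genes with a clear level at each. These levels alone therefore cannot decide on reads carried over between slaughter and fetus. Judged by 5 genes abundant in every fetal library, fetal reads were at most 0.266% of a single F1 library. Slaughter libraries reached 28.55 CPM of ENSBTAG00000012710 and 1.69 CPM of ENSBTAG00000039664, against 30.94 and 8.65 CPM in fetuses. The remaining genes with a gap reached more at slaughter. These values argue against fetal reads in slaughter libraries for these genes. Slaughter reads in fetal libraries were not bounded and stay undecided. Every shared number carried the same treatment label at each stage, and all 15 slaughter numbers recurred among the fetuses. Numbers given by animal would show this, but it does not settle the point. Whether a number marks 1 animal stays open, as no label states it and a batch shared by number was not tested. The birth libraries that matched their own slaughter number best were 2 of 6 over all genes. With gaps of 2-fold, 2.3-fold and 2.8-fold they were 2, 4 and 5, and with 4-fold 6, where the other stage pairs gave 5 of 15 and 2 of 7.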

How the results depend on the processing

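The genes with a wide gap, the fits without fetal MG 20 and LG 41, the unblocked fits over shared numbers, limma voom without weights and the block in the interactions were chosen after seeing the data. LG against MG called 0 genes at each stage under every alternative run, leaving out each library in turn included (0 to 0), except 2 in fetuses in 1 model over all 47 libraries and, at unadjusted p under 0.01 with an absolute log2 fold change over 0.5, 71 at birth, 21 at slaughter and 9 in fetuses; these follow from the looser rule. Over the fits leaving out 1 library, genes at an unadjusted p under 0.05 ran from 378 to 1023 at birth (1023 without LG 05), 215 to 377 at slaughter (377 without LG 07) and 74 to 380 in fetuses (380 without MG 20, 209 without MG 45, 195 without LG 29). Other counts, in that order and partly within these ranges, were, without a filter, 1299, 768 and 887, under the stricter filter 409, 191 and 77, with limma voom and sample weights 659, 365 and 2794, without weights 462, 194 and 118, with 1 surrogate variable 520, 291 and 470, and in 1 model over all libraries 550, 365 and 398. Without fetal MG 20 and LG 41 together, 0 passed, 548 had an unadjusted p under 0.05 and birth against fetus gave 12641. Testing for over 2-fold gave 1839 genes for slaughter against birth and 7079 for birth against fetus, by construction. Numbers are shared by birth and slaughter (6), birth and fetus (7) and slaughter and fetus (15), with the same treatment label under each shared number. Over all genes, 2, 3 and 8 of these pairs correlated above 0.1 (6, 5 and 12 with a 4-fold gap, and all 6 for birth and slaughter from 2.3-fold on). They were therefore not treated as pairing. The treatment labels leave pairing open, as do the gap genes for birth and slaughter. With the number as a block the calls were 7146 of 13756 genes for slaughter against birth and 10814 of 15599 for birth against fetus; without it, over the same libraries and genes, they were 7132 and 10772. The interactions gave 0 with the number as a random block (unadjusted, 166 for birth with slaughter, 218 for slaughter with fetus and 330 for birth with fetus). The mean same-number correlation for birth and slaughter was 0.117 over all genes (exact p = 0.0208) and 0.124 with a 2-fold gap (exact p = 0.104). With 2.3-fold, 2.8-fold and 4-fold it was 0.380, 0.551 and 0.808 (exact p = 0.0208 each). For slaughter and fetus it was 0.0327 over all genes (permutation p = 0.2998) and 0.0265 with a 2-fold gap (permutation p = 0.0868). With gaps of 2.3-fold, 2.8-fold and 4-fold it was 0.139, 0.173 and 0.487 (permutation p = 0.0002, 0.0004 and 0.0005). All these p-values are one-sided. For birth and fetus it was 0.0148 over all genes (exact permutation p = 0.278, one-sided). From a 2-fold gap up it was 0.0519, 0.0788, 0.127 and 0.257 (exact permutation p = 0.0278, 0.00694, 0.0347 and 0.0486, one-sided). The cause was not tested. Gene lists and fetal sex were not run for lack of symbols, nor the slaughter and fetus effect correlation over unshared numbers, as too few remain.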

Other observations

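Genes did not follow 1 course over the 3 stages. Of 15264 genes in the model over 47 libraries, 1745 rose at both steps, where 1694 would if calls at the steps were independent, and 1795 fell at both, where 1924 would. A rise to birth followed by a fall to slaughter was called for 1779 genes (1653 if independent), and a fall followed by a rise for 1971 (1972 if independent). The steps share the birth libraries: their log2 changes correlated with r = -0.107 across genes and a covariance of -0.21, and with different birth libraries for each step, 8 and 8, r was -0.0988 and the covariance -0.19, while unchanged groups simulated with the same sharing gave -0.396 and -0.02. Genes are not independent replicates.

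Reads of fetal origin in F1 libraries can be bounded. Over 5 genes abundant in every fetal library and lowest in F1 libraries, the F1 libraries held at most 0.0876% of the fetal level pooled and 0.266% in a single library.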
